A study of Arabidopsis thaliana with 18 samples.

How the data were processed

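Each of the 18 arrays was hybridized with biotin-labelled cRNA made from 10 µg of total RNA by the standard Affymetrix protocol, per the labels' protocols. Each RNA came from the aerial region of a single plant and was isolated with a plant RNA column kit. The plants grew on solid medium with 1% sucrose at 22 °C, with 16 h of light and 8 h of dark for 17 days. On day 18 they received either 24 h of ultraviolet light (UV) or continuous light, with 8 h of additional light (CO). The harvest of both took place 6 h into the bright phase. Additional light is not stated for the UV plants. Every group of genotype and light held 3 plants, and an array is named here by its group and replicate, as WT_UV 2. P-values thus measure the spread between single plants. The sample titles carry a running code that puts all UV arrays before all CO arrays. The meaning of the code is not given in the sources used here, so its order could not be separated from the light treatment.

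The deposited values were intensities, 1 linear signal for each of 22810 probe sets per array. They ran from 0.01305 to 36000 and were never negative. The authors' scaling was read from the values: the mean without the highest and lowest 2% of probe sets was 500 on every array. Array medians lay between 163 and 185. The software, the background method and the scaling target are not given in the sources used here. No columns of values were left out, and no arrays held identical values. The 64 control probe sets were removed after scaling, which left 22746 probe sets for the tests.

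Probe sets were named only through the supplied annotation table and the supplied table of loci and symbols. Of the tested probe sets, 13513 had 1 gene, 503 had several, and 8730 were not listed. A probe set that is not listed is unnamed here, not without a gene, and no gene was named from a probe set with several. A locus was found for 13436 probe sets, which covered 13286 loci. TT4 and SNG1, the genes after which the mutants are named, have no named probe set here, so a check of the genotypes by name was not analysed here.

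The plan made before the data were examined foresaw log2 values and held a rule for linear ones, which was followed. The linear signals were quantile normalized between arrays in limma 3.58.1 under R 4.3.3, values under 16 were set to 16 (4 on the log2 scale), and log2 was taken. After this, 17.55% of probe sets on each array were at the floor, and 1201 (5.28%) were at the floor on all arrays. The number of arrays per group limits the precision. The median standard error of a difference between groups was 0.178 on the log2 scale, and that of an interaction was 0.252.

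A linear model with the 6 groups as coefficients was fitted to all 18 arrays, which gave 12 residual degrees of freedom. Moderated statistics came from limma's eBayes with default settings. Benjamini-Hochberg adjustment ran over the 22746 probe sets of a comparison, and a probe set with an adjusted p under 0.05 is called changed. The 9 comparisons were UV minus CO in each genotype, each mutant minus WT in each light, and the difference of each mutant's UV effect from that of WT (the interaction). A standard error (SE) comes from this model, so for a given probe set it is shared by comparisons of the same size. Changes are log2 values unless a fold is named. Where all arrays of a group were at the floor, the fold is a lower bound and is written as at least N-fold.

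The rule for named genes was also fixed before the data were examined. For each UV effect it took the 10 largest rises and the 10 largest falls among called probe sets with 1 gene whose groups did not overlap. For each genotype comparison or interaction it took the 5 largest each way. From each gene list it took up to 4 measured members with the smallest adjusted p. TT4 and SNG1 were to be named always. The text names fewer in places, always from the top of a rank. Unnamed probe sets, probe sets with 2 genes, gene families and genes picked for their spread lie outside the rule and were chosen after their values were seen.

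The 25 gene lists fixed before the data were examined held 494 entries, in 21 lists of pathways or responses and 4 lists of tissue markers. Only 77 probe sets of named members were measured, since many members lie on unnamed probe sets. The 4 lists with no measured member were those of flavonoid regulators, camalexin and indole glucosinolates, floral organs, and vascular tissue. For every list the text gives the number of called members over all probe sets and the number when the p-values were adjusted over the list alone. The 15 lists with at least 3 measured members were tested in each comparison with camera, which compares a list with all other genes, with a preset correlation of 0.01 between genes. Camera was repeated with a correlation estimated from the data. Fry, from the same package, was used as well. It tests whether the genes of a list move, on balance, one way, and it does not compare them with other genes.

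The code was tested on simulated data made from the real means and spreads, with 200 changed probe sets in each of 10 draws over 22746 probe sets. These 200 were drawn only from probe sets above the 40th percentile of the mean, so the recovered shares do not cover dimmer ones. For the UV effect in WT, 73.6% of changes of 1 and 95.3% of changes of 2 on the log2 scale were recovered. For tt4 minus WT in CO the shares were 75% and 96.4%, and for the tt4 interaction 53.5% and 89.7%. The share of calls that fell on unchanged probe sets was 8.19%, 8.08% and 6.1% in these 3 comparisons, above the nominal 5%. Without the dimmest probe sets (under the 40th percentile of the mean, 13647 kept) it was 5.89%, 5.15% and 5.24%. That cut lies where the draw of changed probe sets began, so it took out almost only unchanged ones. Probe sets at the floor had almost no variance, and the prior of the moderated test had only 0.748 degrees of freedom.

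RNA quality was read from the control probe sets as the log2 ratio of 3′ to 5′ signal of the GAPDH and actin controls. Differences of these ratios between lights were tested with an exact two-sided permutation test, again without each array in turn and, as a choice made after seeing the data, within each genotype. For comparisons that share the WT arrays, 50 sets of unchanged arrays were simulated and analysed alike. Random lists for the closing section numbered 10000 and were matched on mean value, and shuffles of arrays within groups, made gene by gene, numbered 10000.

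The alternatives planned before the data were examined were quantile normalization of the log2 values, centring each array on its median, leaving out dim probe sets, eBayes with trend and robust settings, array weights, and fitting only the arrays of the groups compared. They also held the replicate number as a block, an adjusted p under 0.01, a log2 change of at least 1 in size, 1 probe set per locus, and leaving out each array in turn. Lists were also tested with the mean of a locus's probe sets. Alternatives added after seeing the data were the values as deposited, a floor of 64, leaving out probe sets at the floor on all arrays, leaving out the 3 arrays with a weight under 0.65 (tt4_UV 3, WT_CO 2 and tt4_CO 2), and tests of gene families and of the plastid genome. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.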

Results

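Transcript levels were measured in the aerial region of 18-day-old Arabidopsis thaliana plants of 3 genotypes: the wild type Col-0 (WT), tt4, which is impaired in flavonoid biosynthesis, and sng1, which is impaired in the synthesis of sinapoyl malate. Flavonoids and sinapate esters are phenylpropanoid compounds that absorb ultraviolet light. Each genotype was sampled after 24 h of ultraviolet light (UV, named UV-B in the series title) and after continuous light (CO), with 3 single plants in each of the 6 groups. The design asks what UV changed in each genotype, how the mutants differed from WT in each light, and whether their UV effects differed. Additional light of 8 h is given for the CO plants and not stated for the UV plants. A change under UV here means UV against CO, and it could not be separated from such a difference in light. Within groups, the correlation of log2 values between arrays ran from 0.972 to 0.991. The first principal component held 48.7% of the variance and separated the lights, with UV arrays from −52.45 to −27.19 and CO arrays from 24.74 to 63.03. The log2 ratio of 3′ to 5′ signal of the GAPDH control was higher under UV (0.0795 ± 0.0806) than in CO (−0.00456 ± 0.0528, SD, n = 9 each, exact permutation p = 0.0117). The difference was 0.168 in WT, 0.0506 in tt4 and 0.0335 in sng1, where 3 arrays against 3 allow no exact p under 0.1. The ratio of the actin control was 1.03 ± 0.31 under UV and 0.821 ± 0.128 in CO (SD, n = 9 each, exact permutation p = 0.0324), with −0.0246 for UV minus CO in tt4. It no longer passed without WT_UV 3 (difference 0.106 in place of 0.206, exact permutation p = 0.0651) or without any 1 of WT_CO 1, WT_CO 2, tt4_CO 3 and the sng1 arrays in CO (0.0578 to 0.0734).

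UV raised a set of WT transcripts by about 10-fold or more (log2 change ± SE, n = 3 against 3 throughout, adjusted p from limma). AT3G48640 rose by 4.11 ± 0.56 (17.3-fold, adjusted p = 0.000278). AT2G04070 and AT2G04050, a pair of genes for MATE transporters, rose by 4.09 ± 0.37 (adjusted p = 2.14e-05) and 3.29 ± 0.58 (adjusted p = 0.0014). AT2G20720 rose by 3.76 ± 0.38 (adjusted p = 4.03e-05), and AT3G28580, which codes for an AAA-type ATPase, rose by 3.40 ± 0.41 (adjusted p = 0.00014). AT1G33860 rose by 3.63 ± 0.19 (adjusted p = 4.38e-07), with 2 of 3 CO arrays at the floor. AT3G13610, the feruloyl-CoA hydroxylase of scopoletin synthesis, rose by 3.32 ± 0.80 (adjusted p = 0.00885). The falls were led by AT3G28270 (−3.56 ± 1.08, adjusted p = 0.0294), AT4G17470 (−3.41 ± 0.52, adjusted p = 0.000583) and IAA29 (−3.36 ± 0.54, adjusted p = 0.000837), which codes for a repressor of auxin responses.

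In all, 5540 of 22746 probe sets (24.4%) changed in WT under UV, 2835 higher and 2705 lower, and 7947 passed at an unadjusted p under 0.05. Among the called, 1484 changed at least 2-fold, 776 higher and 708 lower. They held 2976 probe sets with 1 gene, 119 with several and 2445 unnamed. The call of AT3G28270 ended without WT_UV 2 (−3.34, adjusted p = 0.0907), WT_UV 3 (−3.43, 0.0792), WT_CO 1 (−3.27, 0.09) or WT_CO 3 (−2.75, 0.109), and with the 6 WT arrays fitted alone those of AT3G28270 (adjusted p = 0.11, range over all alternatives 0.00968 to 0.11), AT3G13610 (0.137, range 0.00165 to 0.137) and AT2G04050 (0.0708, range 0.000311 to 0.0708) ended. A floor of 64 reduced the change of AT1G33860 to 1.76 and that of AT4G17470 to −2.00, with the calls kept, and the 6 WT arrays alone gave 2929 calls.

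In tt4, AT3G48640 rose by 6.11 ± 0.56 under UV (68.9-fold, adjusted p = 1.66e-05), with 2 of 3 CO arrays at the floor. AT3G13610 rose by 5.36 ± 0.80 (41.1-fold, adjusted p = 0.00039), also with 2 CO arrays at the floor, and the MATE gene AT2G04070 by 4.75 ± 0.37 (adjusted p = 6.02e-06). AT1G57630, which codes for a protein with a TIR domain as found in immune receptors, rose by 4.46 ± 0.59 (adjusted p = 0.000179). The deepest falls were those of AT1G66100, a thionin gene (−3.07 ± 0.98, adjusted p = 0.0345), AT5G62360 (−2.95 ± 0.59, adjusted p = 0.00244), IAA29 (−2.81 ± 0.54, adjusted p = 0.00208), the transcription factor gene BZIP61 (−2.81 ± 0.49, adjusted p = 0.00111) and AT2G04790 (−2.78 ± 0.34, adjusted p = 0.000106). UV changed 6080 probe sets (26.7%) in tt4, 2879 higher and 3201 lower, of which 1802 changed at least 2-fold (899 higher, 903 lower). The unadjusted count was 8244, and the called held 3235 probe sets with 1 gene, 117 with several and 2728 unnamed. The call of AT1G66100 ended without tt4_UV 3 (−2.25, adjusted p = 0.138), tt4_CO 2 (−2.49, 0.132) or tt4_CO 3 (−3.23, 0.0585), and its adjusted p ran from 0.0129 to 0.358 over all alternatives, the highest without the 3 arrays of low weight (−1.66). A floor of 64 reduced the change of AT3G48640 to 4.35 and that of AT3G13610 to 3.68, with the calls kept. With the 6 tt4 arrays fitted alone the calls of AT1G66100 (adjusted p = 0.112) and AT5G62360 ended (0.0573, range 0.000575 to 0.0573), and 3023 probe sets were called.

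In sng1, AT3G48640 rose by 5.13 ± 0.56 under UV (35-fold, adjusted p = 6.37e-05), the ATPase gene AT3G28580 by 3.97 ± 0.41 (adjusted p = 4.74e-05), AT5G62210 by 3.95 ± 0.29 (adjusted p = 5.34e-06) and AT2G04070 by 3.65 ± 0.37 (adjusted p = 4.07e-05). AT1G13470 rose by 3.62 ± 0.58 (adjusted p = 0.000745). The subtilase gene AT5G58840 was at least 12.1-fold higher (adjusted p = 0.000169), since all 3 CO arrays were at the floor. IAA29 fell by 3.04 ± 0.54 (adjusted p = 0.00155), BZIP61 by 3.03 ± 0.49 (adjusted p = 0.000833) and the expansin gene EXPA8 by 2.63 ± 0.69 (adjusted p = 0.0149). AT5G03120 fell by 2.38 ± 0.32 (adjusted p = 0.000255) and AT2G04790 by 2.26 ± 0.34 (adjusted p = 0.000504). The call of EXPA8 ended without sng1_UV 2 (−2.01, adjusted p = 0.0697) or sng1_CO 2 (−2.22, 0.0682) and with the sng1 arrays fitted alone (0.0866, range over all alternatives 0.0038 to 0.0866). A floor of 64 moved the change of AT3G48640 to 4.02, of AT5G58840 to 1.59, of IAA29 to −1.80 and of EXPA8 to −1.68, with the calls kept. UV changed 5350 probe sets (23.5%) in sng1, 2701 higher and 2649 lower, of which 1380 changed at least 2-fold (743 higher, 637 lower). The unadjusted count was 7694, and the called held 2849 probe sets with 1 gene, 106 with several and 2395 unnamed. With the sng1 arrays fitted alone 5800 probe sets were called, and with array weights 7748.

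Of the 5 measured members of the core flavonoid list, 4 rose and 1 fell in WT, 3 rose in tt4, and 4 rose in sng1. The counts adjusted over the list alone were 4 and 1, 4 and 1, and 4 and 0. AT1G06000, a flavonol rhamnosyltransferase, rose by 2.60 in WT, 2.27 in tt4 and 2.85 in sng1 (± 0.17, adjusted p = 1.67e-06, 4.63e-06 and 7.92e-07). CHIL, a chalcone isomerase-like protein, rose by 2.5, 1.62 and 2.96 (± 0.37, adjusted p = 0.000459, 0.0056 and 0.000155). UGT78D2, a flavonoid glucosyltransferase, rose by 1.18, 1.15 and 1.23 (± 0.17, adjusted p = 0.000432, 4e-04 and 0.000311). UGT78D3 was at least 2.62-fold higher in WT (adjusted p = 0.00674), 0.85 ± 0.32 higher without a call in tt4 (1.28 without tt4_UV 1), and called in sng1 (adjusted p = 0.0213). All its CO arrays were at the floor, and with a floor of 64 its changes in WT and sng1 were 0. UGT78D1 fell by 0.46 ± 0.16 in WT (adjusted p = 0.0497) but was not called with arrays centred on their medians or with the values as deposited, where the list had 4 higher and 0 lower in WT. The sng1 call of UGT78D3 ended without sng1_UV 2 (0.81, adjusted p = 0.0961), sng1_CO 1 (0.0538), sng1_CO 2 (0.0586) or sng1_CO 3 (0.0556). The call of CHIL in tt4 ended without the 3 arrays of low weight (adjusted p = 0.0502, range 5.92e-06 to 0.0502).

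By camera the core flavonoid list was higher than other genes under UV (median 1.39, 1.15 and 1.23 in WT, tt4 and sng1, adjusted p = 0.0123, 0.0337 and 0.00151). The adjusted p was 0.211, 0.432 and 0.0886 with an estimated correlation, so no call held. Fry, which asks only whether the members move one way on balance, gave adjusted p = 1.44e-06, 1.7e-05 and 5.12e-07. In tt4 the camera call also ended without tt4_UV 3 (adjusted p = 0.0641) or tt4_CO 2 (0.0505), and over all alternatives it ran from 0.00895 to 0.432. Among 5 measured members of the anthocyanin branch, none was called in any genotype by limma over all probe sets or over the list alone (camera adjusted p = 0.919, 0.568 and 0.471). AT4G14090, a glucosyltransferase of anthocyanins, had 0.65, 1.00 and 1.36 (± 0.50, adjusted p = 0.413, 0.174 and 0.068). Its WT value was 0.42 without WT_UV 3 and 0.98 without WT_CO 3, and its tt4 value 0.42 without tt4_CO 3 and 1.63 without tt4_CO 2. Of 6 measured genes of the general phenylpropanoid and sinapate ester list, 1 rose and 1 fell in each genotype, and adjusted over the list alone 1 and 1, 1 and 1, and 2 and 1. UGT84A1, which makes glucose esters of hydroxycinnamic acids, was at or below the floor on all CO arrays and at least 7.47-fold, 6.92-fold and 8.13-fold higher under UV (adjusted p = 7.69e-06, 6.92e-06 and 5.2e-06). With a floor of 64 its changes were 0.90, 0.79 and 1.02, with the calls kept. UGT72E1, which glucosylates monolignols, fell by 1.18, 1.01 and 0.98 (± 0.16, adjusted p = 0.000261, 0.000581 and 0.000848). Camera made no call for this list (adjusted p = 0.557, 0.867 and 0.471), and fry gave adjusted p = 0.0316, 0.0917 and 0.0101.

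**Figure D1:**
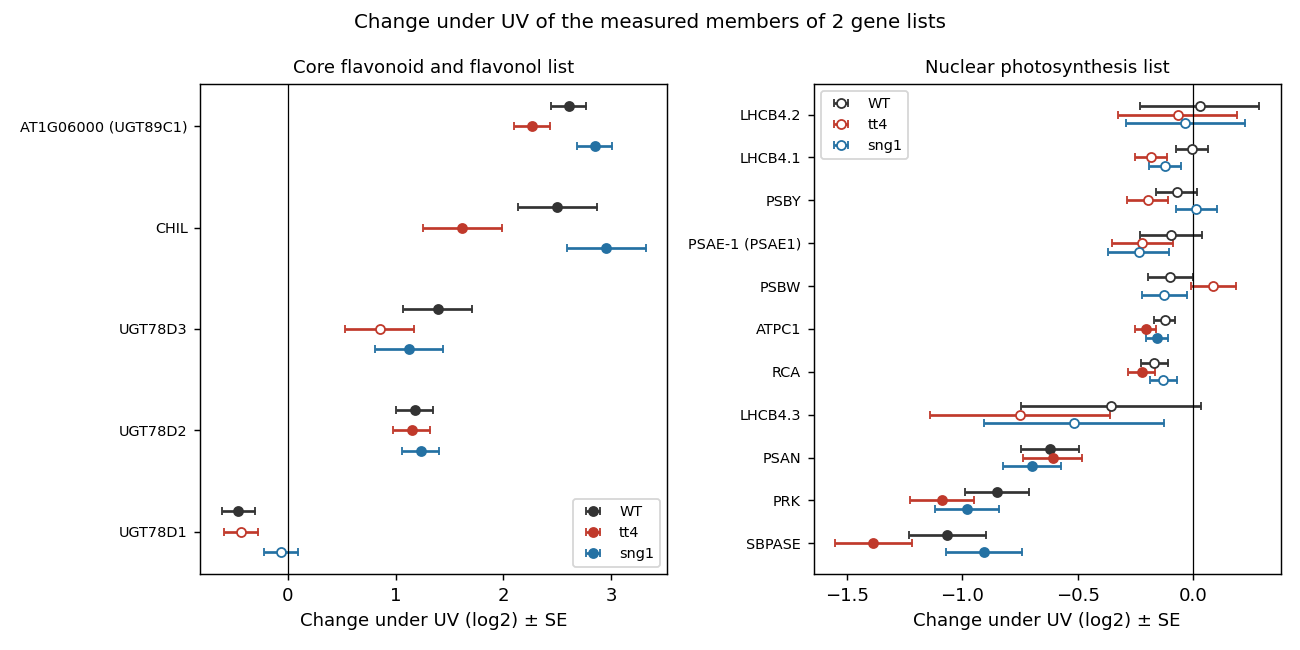
Change under UV (log2, UV minus CO) of the measured genes of the core flavonoid list and of the nuclear photosynthesis list in WT, tt4 and sng1. Points are estimates with bars of ± 1 SE (n = 3 against 3), filled where called at an adjusted p under 0.05. All CO arrays of UGT78D3 were at the floor in all 3 genotypes, so its points depend on the floor, and those in WT and sng1 are lower bounds. SBPASE, PRK and PSAN lie below 0 in all 3 genotypes.

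Of 11 measured nuclear photosynthesis genes, 3 fell in WT, 5 in tt4 and 4 in sng1 under UV, and none rose. When adjusted over the list alone, 5, 6 and 4 were lower. SBPASE and PRK, enzymes of the Calvin cycle, fell by 1.06, 1.39 and 0.91 (± 0.17, adjusted p = 0.000665, 9.73e-05 and 0.00182) and by 0.85, 1.09 and 0.98 (± 0.14, adjusted p = 0.000898, 0.00015 and 0.000357) in WT, tt4 and sng1. PSAN, a subunit of photosystem I, fell by 0.62, 0.61 and 0.70 (± 0.13, adjusted p = 0.00347, 0.00332 and 0.0017). The median of the list was −0.12, −0.22 and −0.16, and the camera adjusted p was 0.0369, 0.00743 and 0.0106. The adjusted p was 0.525, 0.432 and 0.546 with an estimated correlation, and fry gave 0.0145, 0.00172 and 0.00723. The count of lower genes was 5 in WT and 8 in tt4 both with arrays centred on their medians and with the values as deposited, and the GAPDH 3′ to 5′ ratio was 0.0840 higher under UV. Camera's calls ended without WT_UV 2 (adjusted p = 0.0874) or WT_CO 2 (0.0998) in WT and without tt4_UV 3 (0.0539) in tt4, and over all alternatives ran from 0.000518 to 0.525, 1.53e-05 to 0.432 and 0.00432 to 0.546. The sng1 call of ATPC1, a subunit of the plastid ATP synthase (−0.16 ± 0.05, adjusted p = 0.0254), ended without sng1_UV 1 (0.0765), sng1_UV 3 (0.0953), sng1_CO 1 (0.0795) or sng1_CO 2 (0.0953), and the WT call of PRK with WT arrays alone (0.0503).

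Some oxidative stress markers and genes of aromatic amino acid synthesis rose under UV. AT2G21640, a gene known to rise with oxidative stress, rose by 2.76 in WT, 2.74 in tt4 and 2.44 in sng1 (± 0.33, adjusted p = 0.000113, 9.27e-05 and 0.000242). Of 3 measured oxidative stress markers, 1, 2 and 2 rose, and 2 in each genotype adjusted over the list alone. AT2G04400, which codes for an enzyme of tryptophan synthesis, rose by 1.36, 1.62 and 1.60 (± 0.23, adjusted p = 0.000978, 0.000267 and 0.000345). Of 3 measured shikimate pathway genes, 2 rose in each genotype, and 3, 3 and 2 adjusted over the list alone. The camera adjusted p was 0.0431, 0.038 and 0.0426 for each of the lists, and with an estimated correlation the adjusted p was 0.443, 0.432 and 0.524 for oxidative stress and 0.443, 0.432 and 0.531 for the shikimate list. Fry gave 0.000725, 0.000506 and 0.00111 and 0.0029, 0.00128 and 0.00339, and these changes went with the higher GAPDH ratio (difference 0.0840).

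The remaining calls in these lists ended in fits without single arrays, which also had fewer arrays. The zinc finger gene STZ rose in tt4 (1.49 ± 0.41, adjusted p = 0.0158) but not without tt4_UV 2 (0.0509), tt4_CO 1 (0.0636) or tt4_CO 2 (0.0693), and in sng1 (1.23, adjusted p = 0.0448) but not without any 1 of 5 sng1 arrays, all but sng1_CO 3 (0.0808 to 0.158). AT5G66120, a dehydroquinate synthase, rose in WT (0.51 ± 0.16, adjusted p = 0.033) but not without WT_UV 2 (0.0847), WT_UV 3 (0.129), WT_CO 1 (0.0877) or WT_CO 2 (0.105). AT1G22410, an enzyme at the entry of the shikimate pathway, rose in tt4 (0.46 ± 0.13, adjusted p = 0.0163) but not without tt4_UV 3 (0.0681) or tt4_CO 2 (0.0587), and in sng1 (0.49, adjusted p = 0.013) but not without sng1_UV 2 (0.0609). In WT the camera calls of both lists ended without WT_UV 2 (0.0874) or WT_CO 2 (0.0998), that of oxidative stress also without WT_UV 1 (0.0539) and that of the shikimate list without WT_UV 3 (0.0559). In tt4 both ended without tt4_UV 3 (0.0673) or tt4_CO 2 (0.0505 and 0.054), and that of oxidative stress also without tt4_UV 2 (0.0556) or tt4_CO 1 (0.0609). In sng1 each ended without any 1 of 5 arrays (0.0506 to 0.0716), the exceptions being sng1_CO 1 for oxidative stress and sng1_UV 1 for the shikimate list. Over all alternatives the camera adjusted p of these lists ran from 0.0137 in WT, 0.0162 in tt4 and 0.0256 in sng1 up to the values with an estimated correlation.

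Single members of further lists rose under UV in all genotypes, and the GAPDH ratio was 0.0840 higher there. HYH, a transcription factor related to HY5, was 1 of 2 measured genes of UV-B signalling and rose by 1.92 in WT, 1.15 in tt4 and 1.99 in sng1 (± 0.37, adjusted p = 0.00232, 0.0334 and 0.00185), and by 1.05, 0.73 and 1.24 with a floor of 64. ATLIG4, the ligase of DNA end joining, was 1 of 2 measured DNA repair genes and rose by 0.83, 0.63 and 0.68 (± 0.11, adjusted p = 0.000288, 0.00133 and 0.000917). The counts of both lists were the same adjusted over the list alone. WRKY6 rose by 1.02, 1.38 and 1.64 (± 0.23, adjusted p = 0.00711, 0.000939 and 0.00037) while NOL, a reductase of chlorophyll b, fell by 0.61, 0.70 and 0.64 (± 0.14, adjusted p = 0.0059, 0.00219 and 0.00444). They were 2 of 3 measured senescence genes, also adjusted over the list alone, and in sng1 the median of that list (−0.64) and its mean (0.08) differed in sign. Of 2 measured genes of salicylic acid defence, SAG101 rose by 1.26, 1.36 and 0.89 (± 0.27, adjusted p = 0.00416, 0.00221 and 0.0285), WRKY53 was called in tt4 (1.67 ± 0.49, adjusted p = 0.022) and sng1 (1.64, adjusted p = 0.0268), and both genes were called in each genotype adjusted over the list alone. The tt4 call of HYH ended without any 1 of 5 tt4 arrays, all but tt4_CO 3 (adjusted p 0.0605 to 0.146, lowest change 0.79 without tt4_CO 2). That of WRKY53 in tt4 ended without tt4_UV 1 (0.0815), tt4_UV 2 (0.0623) or tt4_CO 2 (0.0769), in sng1 without sng1_UV 1 (0.0847), sng1_UV 3 (0.069), sng1_CO 1 (0.102) or sng1_CO 2 (0.0642), and that of SAG101 in sng1 without sng1_UV 2 (0.0937), sng1_UV 3 (0.0735), sng1_CO 1 (0.0818) or sng1_CO 2 (0.0875).

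Antioxidant enzymes went both ways. GR1, a glutathione reductase, rose by 1.77, 1.64 and 1.80 in WT, tt4 and sng1 (± 0.25, adjusted p = 0.000387, 0.000501 and 0.000323), and TAPX, the thylakoid ascorbate peroxidase, fell by 1.08, 1.27 and 1.13 (± 0.21, adjusted p = 0.00277, 0.000855 and 0.00212). Of 6 measured, 1 rose and 2 fell in WT and tt4, and 2 rose and 1 fell in sng1. Adjusted over the list alone the counts were 2 and 2, 1 and 2, and 2 and 1, and in tt4 camera and fry pointed in opposite directions without a call (adjusted p = 0.961 and 0.928). The peroxiredoxin gene AT3G11630 fell by 0.32 ± 0.09 in WT (adjusted p = 0.0153) but not without WT_UV 2 (0.072), WT_CO 1 (0.0545) or WT_CO 2 (0.0604), and GR rose by 0.29 ± 0.10 in sng1 (adjusted p = 0.0458) but not without any 1 of 5 arrays, all but sng1_UV 1 (0.0698 to 0.18). Of 4 measured genes of aliphatic glucosinolate synthesis, 1 rose in WT, 1 rose and 2 fell in tt4, and 1 rose and 1 fell in sng1. With arrays centred on their medians and with the values as deposited, 1 rose and 3 fell in tt4, and 1 rose and 0 fell in sng1. The counts adjusted over the list alone were 1 and 2, 1 and 3, and 1 and 2. UGT74B1, a glucosyltransferase of that pathway, rose by 0.61, 0.65 and 0.91 (± 0.18, adjusted p = 0.0229, 0.0144 and 0.0025), and AT2G31790 fell in tt4 (−0.72 ± 0.13, adjusted p = 0.00165). The call of UGT74B1 ended in WT without WT_UV 2 (0.103), WT_UV 3 (0.0583), WT_CO 1 (0.0781) or WT_CO 2 (0.0978) and in tt4 without tt4_CO 2 (0.055). BCAT4, an aminotransferase of the same pathway, fell by 1.75 ± 0.43 in tt4 (adjusted p = 0.00832) and by 1.27 in sng1 (adjusted p = 0.0463), the latter not without any 1 of the 6 sng1 arrays (0.058 to 0.134).

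Among tissue markers, FMA, a regulator of guard cell formation, fell under UV by 0.62, 0.65 and 0.66 in WT, tt4 and sng1 (± 0.14, adjusted p = 0.00519, 0.00322 and 0.00349). SPCH, which starts the stomatal lineage, fell by 1.04 ± 0.25 in WT (adjusted p = 0.00923), with 0.05 in sng1 (−0.03 to 0.19 without single sng1 arrays). Thus 2, 1 and 1 of 3 measured stomatal markers fell, also adjusted over the list alone, without a camera call (adjusted p = 0.117, 0.378 and 0.471). The interaction of SPCH in sng1 was 1.09 ± 0.36 (adjusted p = 1 over all probe sets, 0.0279 over the list alone), and without the 3 arrays of low weight its WT call ended (0.0675), as it did with the WT arrays fitted alone (0.146, range 0.00367 to 0.146). PYK10, an abundant root glucosidase, was the called root marker of 3 measured, in tt4 (−1.60 ± 0.42, adjusted p = 0.0125), a call that ended without tt4_UV 1 (−1.18, 0.0542). In WT and in tt4, 1 root marker fell when adjusted over the list alone. Of 4 measured genes of auxin and shade responses IAA29 alone was called, also adjusted over the list alone, and in tt4 their median (0.13) and mean (−0.31) differed in sign. Of 3 measured cell cycle genes, AUR1 fell in WT (−0.65 ± 0.22, adjusted p = 0.0465) but not without any 1 of 5 WT arrays, all but WT_CO 3 (0.0505 to 0.195, with −0.40 without WT_CO 2), and PRL fell in tt4 (−0.40 ± 0.12, adjusted p = 0.0296) but not without tt4_UV 2 (0.0737), tt4_UV 3 (0.0781), tt4_CO 2 (0.115) or tt4_CO 3 (0.0685). Adjusted over the list alone, 2, 1 and 0 cell cycle genes fell.

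With the arrays of 1 genotype fitted alone, further calls of list members ended, and the values that follow are the range of each adjusted p over all alternatives, with its upper end in that setting. In WT these were WRKY6 (0.0025 to 0.0825), FMA (0.000643 to 0.0784), TAPX (0.000882 to 0.0531), AT3G11630 (0.00223 to 0.103), UGT74B1 (0.0059 to 0.171), AT2G04400 (0.000209 to 0.0565) and NOL (0.00284 to 0.0531). In tt4 they were BCAT4 (0.00251 to 0.147), SAG101 (0.000614 to 0.0718), STZ (0.003 to 0.0932), GR1 (0.000104 to 0.0501), AT2G31790 (0.000779 to 0.059), NOL (0.000353 to 0.0602) and PYK10 (0.00128 to 0.138). Other calls ended there with higher values elsewhere: in WT AT5G66120 (adjusted p = 0.0849, range 0.0184 to 0.129) and AUR1 (0.171, range 0.0229 to 0.195), in tt4 HYH (0.179, range 0.00279 to 0.274), PRL (0.0551, range 0.0216 to 0.221) and AT3G11630 (0.0745, range 0.000926 to 0.106), and in sng1 UGT78D3 (0.0611, range 0.00577 to 1), GR (0.0654, range 0.00882 to 0.18) and ATPC1 (0.0565, range 0.00423 to 0.123).

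Without the 3 arrays of low weight the tt4 calls of HYH (0.73, adjusted p = 0.274), PRL (0.221), AT3G11630 (0.106), AT1G22410 (0.131, range 0.0111 to 0.131), UGT74B1 (0.0997, range 0.00686 to 0.0997), PSAN (0.0606, range 0.000468 to 0.0606) and ATPC1 (0.055, range 0.000109 to 0.055) ended. So did those of AT3G11630 (0.0507), UGT74B1 (0.127) and AUR1 (−0.40, 0.143) in WT and of GR (0.0814) in sng1. With array weights HYH (0.0548) and PRL (0.0909) were not called in tt4, nor AUR1 (0.0646) in WT. The replicate number as a block also ended the tt4 call of HYH (0.0537). ATPC1 was not called in sng1 without dim probe sets (0.11) or without those at the floor on all arrays (0.123), and GR not without the latter (0.0628). Calls close to the threshold ended with a floor of 64 or 1 probe set per locus, namely AUR1 in WT (0.0537 and 0.052) and STZ (0.0513 and 0.0506), GR (0.0502 and 0.0508) and BCAT4 (0.0531 and 0.0523) in sng1, where over all alternatives STZ ran from 0.00965 to 0.158 and BCAT4 from 0.00737 to 0.134. AUR1 in WT (0.0568) and BCAT4 in sng1 (0.0606) were also not called with arrays centred on their medians, and BCAT4 not with the values as deposited (0.05). In these scalings (centred and deposited, in that order) AT3G11630 fell by 0.49 and 0.55 in WT and by 0.60 and 0.59 in tt4, and ATPC1 by 0.52 and 0.51 in tt4 and by 0.24 and 0.32 in sng1.

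By limma, 0 of 5 measured heat shock, 3 abscisic acid, cold and drought, 2 jasmonate, 1 clock and 1 wax gene were called under UV in any genotype. Adjusted over the list alone, 1 heat shock gene rose and 1 fell and 1 jasmonate gene rose, all in WT. In the other scalings 1 heat shock gene was called lower in WT. The values of GI, the clock gene, were 0.46, 0.46 and 0.58 (± 0.29, adjusted p = 0.289, 0.285 and 0.178) and those of the cold-response gene COR15A were −2.11, 0.99 and −1.98 (± 1.07, adjusted p = 0.186, 0.582 and 0.225). The tt4 value of COR15A was −0.32 without tt4_CO 3, 0.34 without tt4_UV 3 and 2.25 without tt4_CO 1, while GI had 0.13 in WT without WT_CO 1, and in tt4 0.23 without tt4_CO 3 and 0.79 without tt4_CO 2. In tt4 the median (−0.10) and the mean (0.07) of the abscisic acid list differed in sign, and the median ran from −0.86 (without tt4_CO 3) to 0.49 (without tt4_CO 2). At an unadjusted p under 0.05, 7947, 8244 and 7694 probe sets passed in WT, tt4 and sng1.

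The UV effects of the 3 genotypes, which share no arrays, were similar across probe sets. The correlation of log2 changes across probe sets, which are not independent replicates, was 0.831 between WT and tt4, 0.849 between WT and sng1 and 0.824 between tt4 and sng1. Probe sets called in the same direction in all 3 genotypes numbered 3528, of which 1760 were higher (42.61 for independent lists) and 1768 lower (44.33 for independent lists), out of 8097 called in at least 1. AT3G48640, AT2G04070 and AT3G28580 were among the shared rises and IAA29 and SBPASE among the shared falls. WT and tt4 shared 2108 rises and 2144 falls (358.8 and 380.7 for independent lists), WT and sng1 2108 and 1975 (336.6 and 315), and tt4 and sng1 1972 and 2088 (341.9 and 372.8). Each pair had 2 probe sets called in opposite directions. A probe set called in 1 genotype and not in another is not shown to differ: the interaction test called 1 probe set in tt4 and 0 in sng1, where 1032 and 688 passed at an unadjusted p under 0.05 in limma.

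**Figure D2:**
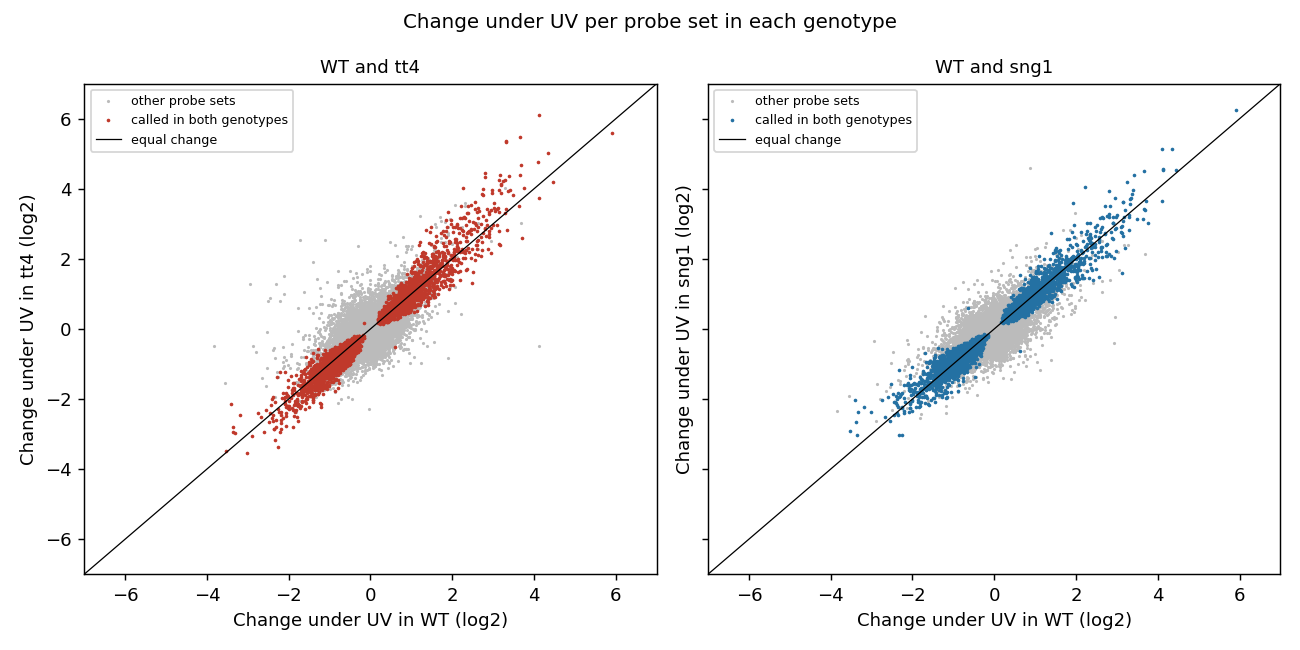
Change under UV (log2, UV minus CO) of each probe set in WT on the horizontal axis and in tt4 or sng1 on the vertical axis, with probe sets called in both genotypes of a panel in colour. The points lie along the diagonal, with correlations across probe sets of 0.831 and 0.849.

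Among the calls between genotypes, the largest difference was that of 250207_at, an unnamed probe set chosen after its values were seen. Whether it measures TT4 itself could not be checked here. UV raised it by 4.13 ± 0.26 in WT (17.5-fold, adjusted p = 1.39e-06) and by 4.56 ± 0.26 in sng1 (adjusted p = 6.2e-07), while tt4 had −0.49 ± 0.26 (adjusted p = 0.189). Its mean signal was 8773 ± 608 in WT and 8573 ± 535 in sng1 under UV, and 187 ± 31.6 in tt4 (SD, n = 3). In CO it was 505.5 ± 81.2 in WT, 394 ± 201 in sng1 and 261 ± 16.3 in tt4 (SD, n = 3). Under UV tt4 was thus 5.57 ± 0.26 below WT (−5.57, 47.4-fold, adjusted p = 4.2e-07), and the interaction was −4.62 ± 0.36 (24.6-fold, adjusted p = 0.000279). The interaction kept its call in all 23 alternatives that test this probe set (−4.75 to −4.51, adjusted p up to 0.00515). It was the only interaction called for tt4 (1032 at an unadjusted p under 0.05), and 2 to 7 were called without any 1 of 11 of the 12 arrays, all but WT_UV 3, with 7 without WT_CO 3.

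Under UV, tt4 differed from WT in 3 probe sets, all lower in tt4, and 1083 passed at an unadjusted p under 0.05. Beside 250207_at these were AT3G58050 (−0.20 ± 0.03, adjusted p = 0.0248) and the unnamed 260973_at (−1.74 ± 0.19, adjusted p = 0.00663), which had 2 of 3 tt4 arrays at the floor and −0.07 with a floor of 64. No list was called by camera, fry or limma in this comparison. The call of AT3G58050 ended without WT_UV 2 (0.0642), WT_UV 3 (0.0567), tt4_UV 1 (0.0775) or tt4_UV 3 (0.0764), and its adjusted p ran from 0.00805 to 0.999 over all alternatives. It was also not called with arrays centred on their medians (0.335), as deposited (0.241), without dim probe sets (0.999) or with the arrays of the compared groups alone (0.783), where the call of 260973_at ended too (0.783, range 0.00262 to 1). The number of calls was 13 without WT_UV 1, 8 without WT_UV 2, 7 without WT_UV 3, and 6 without tt4_UV 1, tt4_UV 2 or tt4_UV 3.

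In CO, tt4 differed from WT in 5 probe sets, 4 higher and 1 lower in tt4. AT5G34800 was higher by 1.67 ± 0.23, with 2 of 3 WT arrays at the floor, AT2G25990 was higher by 0.75 ± 0.09, with 1 of 3 WT arrays at the floor, and AT1G13195 was lower by 0.82 ± 0.11 (adjusted p = 0.0352 each). The unnamed 247127_at and 254450_at were higher by 0.50 ± 0.06 and 0.59 ± 0.08 (adjusted p = 0.0352 and 0.036), the latter with 2 of 3 WT arrays at the floor. With a floor of 64 the difference of AT5G34800 was 0.03 and those of AT2G25990 and 254450_at were 0 (adjusted p = 1 each). At an unadjusted p under 0.05, 1045 passed. With arrays centred on their medians 1 was higher and 3 were lower, and with the values as deposited 1 and 5. Measured anthocyanin genes had a median of −0.75 and those of the abscisic acid, cold and drought list −1.42, with camera adjusted p = 0.0464 each, 0.64 each with an estimated correlation, and 0.829 each by fry. None of their members was called, over all probe sets or over the list alone. DFR, which makes leucoanthocyanidins, had −0.99 ± 0.51 and COR15A −2.15 ± 1.07 (adjusted p = 1 each). Without tt4_CO 3 they had −0.33 and −0.83, and the medians of the lists were −0.33 and −0.48. Without tt4_CO 2 DFR had −1.67 and the median of the anthocyanin genes was −1.17, and without tt4_CO 1 COR15A had −3.41.

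These calls rested on few arrays. AT5G34800 was not called without WT_CO 1 (0.0635), WT_CO 2 (0.115), WT_CO 3 (0.0524), tt4_CO 1 (0.0762) or tt4_CO 2 (0.0658), and its adjusted p ran from 0.0138 to 1 over all alternatives. AT1G13195 was not called without WT_CO 1 (0.0635), WT_CO 3 (0.0524), tt4_CO 1 (0.0762) or tt4_CO 2 (0.0637), with a range of 0.00184 to 0.894, and AT2G25990 not without WT_CO 1 (0.0556), with a range of 0.00144 to 1. The probe set 247127_at was not called without WT_CO 2 (0.0947), WT_CO 3 (0.0513) or tt4_CO 1 (0.0505), and 254450_at not without any array of the comparison other than tt4_CO 3 (0.054 to 0.119), with ranges of 0.0129 to 0.894 and 0.0228 to 1. With the arrays of the compared groups alone none of the 5 was called (0.835 to 0.934), and AT5G34800, AT2G25990 and 254450_at were not called with arrays centred on their medians (0.0746, 0.311 and 0.115) or as deposited (0.118, 0.44 and 0.232). Without the 3 arrays of low weight AT5G34800 (0.211), 247127_at (0.0897) and 254450_at (0.162) were not called, and without dim probe sets AT1G13195 (0.0608) and 247127_at (0.258) were not. The camera call of the anthocyanin genes ended without WT_CO 1 (0.0639), WT_CO 2 (0.163), WT_CO 3 (0.333), tt4_CO 1 (0.218) or tt4_CO 3 (0.486), and that of the abscisic acid list without WT_CO 1 (0.275), WT_CO 2 (0.163), WT_CO 3 (0.116) or tt4_CO 3 (0.473), with ranges of 5.6e-06 to 0.789 and 0.011 to 0.64 over all alternatives. Both also ended with the arrays of the compared groups alone (0.196 each) and with the values as deposited (0.103 and 0.12), and that of the anthocyanin genes with a floor of 64 (0.789). The number of called probe sets was 16 without WT_CO 3 and 15 without tt4_CO 3.

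In sng1, a pair of unnamed probe sets, chosen after their values were seen, was lower than in WT in both lights. Whether either of them measures SNG1 itself could not be checked here. In CO, 267262_at was lower by 4.29-fold (−2.10 ± 0.21) and 252331_s_at by 3.67-fold (−1.87 ± 0.19, adjusted p = 0.00281 each), and these were the 2 calls, with 1159 at an unadjusted p under 0.05. Under UV they had −2.02 ± 0.21 and −1.90 ± 0.19 (adjusted p = 0.00355 each). Their mean signals in WT and sng1 were 3530 and 834 for 267262_at and 432 and 123 for 252331_s_at in CO. With the values as deposited, 1 probe set was higher and 7 were lower in CO. Over all alternatives the adjusted p ran from 0.00026 to 0.421 for 267262_at and 0.000169 to 0.443 for 252331_s_at in CO, and from 0.000301 to 0.409 and 0.000301 to 0.116 under UV. The highest values came with the arrays of the compared groups fitted alone, and without the 3 arrays of low weight the calls ended too (0.0677 and 0.0699 under UV, 0.054 for 252331_s_at in CO). The number of calls in CO was 10 without WT_CO 1, 6 without WT_CO 2, 21 without WT_CO 3, 4 without sng1_CO 1 and 6 without sng1_CO 2.

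**Figure D3:**
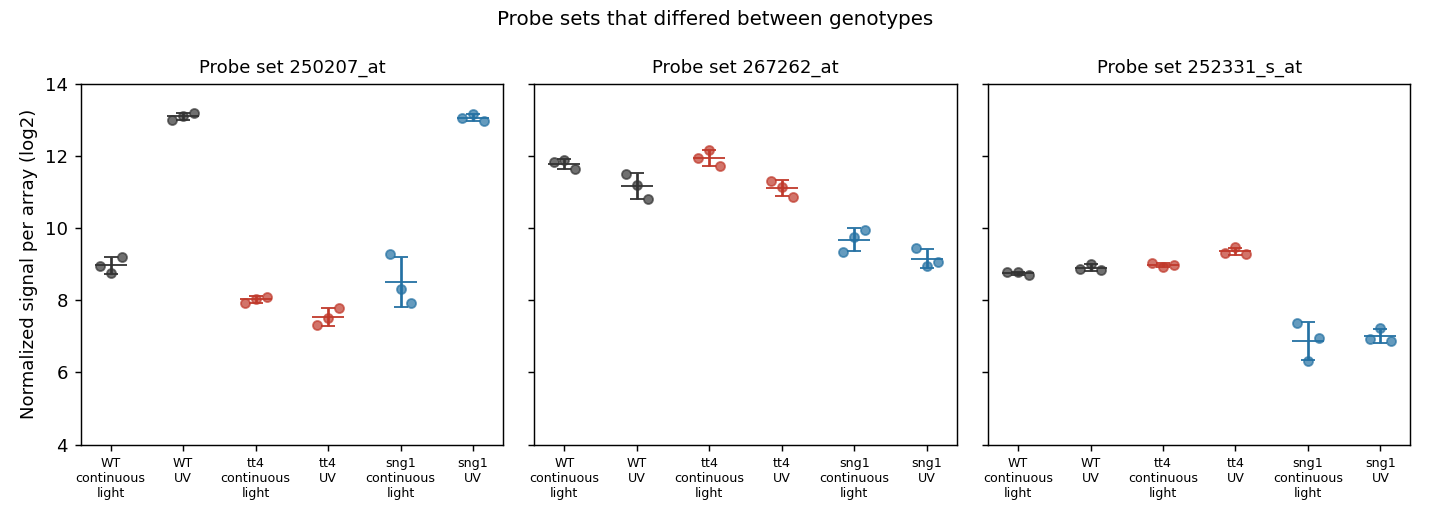
Log2 values on single arrays (points) with group mean and bars of ± 1 SD (n = 3) of the unnamed probe sets 250207_at, 267262_at and 252331_s_at in the 6 groups of genotype and light. The 3 tt4 arrays under UV lie below all WT and sng1 arrays under UV for 250207_at, and the sng1 groups have the lowest means of 267262_at and 252331_s_at in each light.

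Under UV, 5 probe sets differed between sng1 and WT, all lower in sng1, and 1010 passed at an unadjusted p under 0.05. Beside the pair above, AT3G58050 was lower (−0.22 ± 0.03, adjusted p = 0.0115, 0.00246 to 1 over all alternatives, with 0.18 when arrays were centred on their medians and 0.06 as deposited), as was a pair of probe sets listed with 2 genes each (−0.98 ± 0.13 and −0.92 ± 0.13, adjusted p = 0.0286 and 0.0461). The stomatal gene SPCH had 1.06 ± 0.25 (adjusted p = 0.948, and 0.00327 adjusted over the list alone). No list was called by camera or fry in either light or in either interaction. The call of the first of that pair ended without WT_UV 3 (0.0859), sng1_UV 1 (0.098), sng1_UV 2 (0.0666) or sng1_UV 3 (0.0801), and that of the other without any 1 of 5 arrays, all but WT_UV 2 (0.0862 to 0.157). Among the settings that leave out no single array, 4 and 6 ended these calls as well. Over all alternatives the adjusted p ran from 0.00867 to 0.174 and from 0.00867 to 0.528. The number of calls was 12 without WT_UV 1, 10 without WT_UV 2 and 8 without sng1_UV 1. For the interaction of sng1 with UV limma made 0 calls (688 at an unadjusted p under 0.05), and 1 to 7 without any 1 of 11 of the 12 arrays, all but sng1_CO 2, with 7 without WT_CO 3. In tt4 PDF1.2, a defensin gene of the jasmonate list, had an interaction of −2.73 ± 1.02 (adjusted p = 1, and 0.038 adjusted over the list alone).

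The mutants were compared with the same WT arrays. AT3G58050 was the 1 probe set called lower in both mutants under UV, against 0.02 on average and at most 1 in the 50 simulated sets of unchanged arrays, and 0.00066 for independent lists. The correlation of the differences of both mutants across probe sets was 0.386 in CO, 0.463 under UV and 0.428 for the interaction, against simulated medians of 0.501, 0.5 and 0.5. The covariance was 0.0228, 0.0268 and 0.0486, against 0.0319, 0.0316 and 0.0632 in the simulation. The 3 WT arrays of a light cannot be split into parts of at least 2 arrays, so part of the shared call may come from the shared WT arrays.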

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

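The test for mislabelled arrays was chosen after its result was seen; the test of scaling and those of other splits were set before.

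A difference between the UV effects of WT and tt4 past the threshold of the interaction test drew attention to the unnamed probe set 250207_at, with an interaction of −4.62 (adjusted p = 0.000279). Scaling of the tt4 arrays under UV is argued against by the 285 probe sets as bright in WT under UV, which in the deposited values differed between tt4 and WT by a median of −0.0397 (−0.444 to 0.324), while 250207_at itself differed by −5.49. All 3 tt4 arrays under UV lay below all 6 WT and sng1 arrays under UV. A probe set picked for so large a difference with so small a spread would show this anyway. It is thus no separate test of a mislabelled array. A candidate explanation is the tt4 genotype itself, as a hypothesis found and tested on the same arrays. Which gene this probe set measures is not known here, and a difference in the probed sequence of the mutant was not tested. TT4 has no named probe set here, so 250207_at may measure the mutated gene itself. A response of another gene to the loss of TT4 is thus not shown.

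For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The UV effects called 5540 probe sets in WT, 6080 in tt4 and 5350 in sng1, and the highest of the other splits called 4, 4 and 1; in each case 1 split, the real one, gave as many. For tt4 minus WT in CO the real split called 5 and 4 splits gave as many. The highest of the others called 32, which set WT_CO 1, WT_CO 3 and tt4_CO 1 apart from WT_CO 2, tt4_CO 2 and tt4_CO 3. A structure of these samples that does not follow genotype could give this. Deviations within groups correlated by 0.545 for WT_CO 2 with tt4_CO 2, 0.518 for WT_CO 3 with tt4_CO 1 and −0.57 for WT_CO 2 with tt4_CO 1. The array tt4_CO 3 did not follow the split, with −0.0904 for WT_CO 2 and 0.173 for WT_CO 1. Whether such a structure gave the 32 calls, and its cause, were not tested. For tt4 minus WT under UV the real split called 3 and 3 splits gave as many. The highest called 10, with WT_UV 1, tt4_UV 1 and tt4_UV 2 apart from WT_UV 2, WT_UV 3 and tt4_UV 3. The real split called 13 without WT_UV 1, so no structure is read from a count of this size. For sng1 minus WT, the real splits called 2 in CO, where 2 splits gave as many and the highest other called 2, and 5 under UV, where 1 split gave as many and the highest other called 2. For the interactions, 100 splits of the genotypes within each light were drawn, the real one included. The tt4 interaction called 1 probe set, 51 of the 100 splits gave as many and the highest other called 13, so chance is not excluded as the source of a count of that size. The sng1 interaction called 0 in limma (688 at an unadjusted p under 0.05), a number that 100 of the 100 splits reached, and the highest other called 4.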

How the results depend on the processing

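The settings chosen after seeing the data were the values as deposited, the floor of 64, leaving out probe sets at the floor on all arrays and leaving out the 3 arrays of low weight; the others were planned. No result reversed its direction once called. With the arrays of the compared groups alone, UV called 2929 probe sets in WT and 3023 in tt4 but 5800 in sng1, tt4 minus WT 0 in CO and 1 under UV, sng1 minus WT 0 and 1, and the sng1 interaction 2. An adjusted p under 0.01 left 3099, 3729 and 3092 for UV in WT, tt4 and sng1, 0 for tt4 minus WT in CO and 2 for sng1 minus WT under UV, and a log2 change of at least 1 left 1484, 1802, 1380, 1 and 2, and 854 of the 3528 shared UV effects. With 1 probe set per locus, which tests fewer probe sets, the counts were 2822, 3101 and 2723 for UV, 3 and 1 for tt4 minus WT, 0 and 1 for sng1 minus WT, and 0 for the tt4 interaction. Leaving out dim probe sets gave 0 and 1 for tt4 minus WT in CO and under UV, and 3 camera calls of gene lists in place of 14. With array weights UV called 5578 probe sets in WT, 5336 in tt4 and 7748 in sng1. Both this setting and the compared groups alone thus gave the most UV calls in sng1, which had the fewest in the main fit. For sng1 minus WT in CO, array weights gave 9 calls, arrays centred on their medians 5 (2 under UV) and the values as deposited 8 (3 under UV). A floor of 64, or leaving out probe sets at the floor on all arrays, gave 3 for tt4 minus WT in CO. Without the 3 arrays of low weight there were 11 and 8 calls for tt4 minus WT, 6 and 0 for sng1 minus WT, 10 and 4 for the interactions of tt4 and sng1, and 9 for the gene lists; with an estimated correlation 0 lists were called by camera. The cause was not tested for the compared groups alone, the scalings, weights and floors. Counts of 0 are from limma or camera, with 1045, 1159, 1010 and 1032 probe sets at an unadjusted p under 0.05 for tt4 minus WT in CO, sng1 minus WT in CO and under UV, and the tt4 interaction.

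Leaving out 1 array in turn gave 4029 to 5330 calls for UV in WT, 4791 to 5751 in tt4 and 3881 to 4367 in sng1. It gave 6 to 16 and 6 to 13 for tt4 minus WT in CO and under UV, 3 to 21 and 7 to 12 for sng1 minus WT, and 1 to 7 and 0 to 7 for the interactions of tt4 and sng1. The highest counts came without WT_CO 3 in CO (16 and 21) and for the interactions (7 each), and without WT_UV 1 under UV (13 and 12). The shared UV effects numbered 2835 to 3481 and the list calls 7 (without tt4_UV 2 or tt4_UV 3) to 13, with 9 without WT_UV 3, sng1_UV 2 or WT_CO 2. Of 154 called results, each a named gene or a probe set in 1 comparison, 91 kept the call under every setting that tested it at an adjusted p under 0.05. The stricter thresholds (an adjusted p under 0.01, a log2 change of at least 1) were not counted there. Of the UV calls, 4916 in WT, 5719 in tt4 and 4722 in sng1 remained with arrays centred on their medians. Signals near the floor limit what dim probe sets can show, and simulated data gave 8.19% of calls on unchanged probe sets for UV in WT, above the nominal 5%.

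With the replicate number as a block, UV called 5421, 5952 and 5226, tt4 minus WT 0 in CO (adjusted p = 0.111 for each of its 5) and 3 under UV, sng1 minus WT 2 and 3, the interactions 1 and 0, and the gene lists 8. Of the 3 calls for tt4 minus WT under UV, 2 were also calls of the main fit. The 45 pairs of same-numbered arrays had correlations of −0.546 to 0.545, 14 of them over 0.1, and 6 of 18 arrays correlated best with an array of their own number, so the numbers were not taken as pairs.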

Other observations

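The gene families, picked from 29 tested, the plastid genome and the genes with the largest spread were chosen after seeing the data. So were the tests of scaling, bright probe sets and dim probe sets for them, while the tests of RNA quality were set before. Single members were not tested again without single arrays.

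The signal of many genes of the plastid genome fell under UV. Of 69 measured, 41 were lower in WT, 47 in tt4 and 35 in sng1, with none higher (median −0.44, −0.60 and −0.41), while the GAPDH 3′ to 5′ ratio was 0.0840 higher under UV. In WT rpoB, a subunit of the plastid RNA polymerase, fell by 1.38 ± 0.15 (SE, n = 3 against 3, adjusted p = 7.5e-05 in limma), and rps14, a ribosomal protein, by 1.28 ± 0.17 (adjusted p = 0.000211). In tt4 ndhH, a subunit of the NDH complex, fell by 1.73 ± 0.22 (adjusted p = 0.000129). In WT, tt4 and sng1, cemA fell by 0.71, 0.86 and 0.78 (± 0.09, adjusted p = 0.000231, 5.29e-05 and 0.000114). Camera gave adjusted p = 9.5e-18, 2.4e-16 and 1.59e-11 and, with an estimated correlation, adjusted p = 0.184, 0.227 and 0.37, and fry gave 8.79e-05, 4.94e-05 and 0.000825. With arrays centred on their medians 53, 59 and 29 were lower, with the values as deposited 55, 59 and 39, and none higher.

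Several families of nuclear genes held members that fell or rose under UV. Over all probe sets, 24.4% were called under UV in WT, 26.7% in tt4 and 23.5% in sng1, in either direction. RALFL33 and RALFL34, genes for small signalling peptides, fell by 0.97, 1.16 and 1.33 (± 0.11, adjusted p = 0.000101, 2.43e-05 and 1.25e-05) and by 1.21, 1.34 and 1.05 (± 0.15, adjusted p = 0.000152, 6.39e-05 and 0.00037) in WT, tt4 and sng1. Of 10 RALFL genes 4 fell in each genotype, with 3, 4 and 3 when arrays were centred on their medians, and none rose in any scaling. Of 10 expansin genes, 3, 4 and 3 fell in each of the scalings, among them EXPA16 (−1.69, −1.37 and −2.12, ± 0.35). Of 15 IQD genes, for calmodulin-binding proteins, 8, 5 and 5 fell and 0, 1 and 1 rose, with 7, 5 and 4 lower when arrays were centred on their medians. The gene iqd21 fell by 1.41, 1.29 and 1.00 (± 0.22, adjusted p = 0.000636, 0.000928 and 0.00519). Of 10 VPS genes of vesicle sorting, 4 rose and 1 fell in each genotype, with 4 and 0, 4 and 1, and 5 and 1 when arrays were centred on their medians. VPS60.1 rose by 1.1, 1.05 and 0.74 (± 0.08, adjusted p = 4.61e-06, 5.64e-06 and 6.43e-05). Camera gave adjusted p = 0.0593, 0.108 and 0.161 for RALFL, 0.144, 0.26 and 0.172 for expansins, 0.0206, 0.0748 and 0.172 for IQD (0.225, 0.362 and 0.503 with an estimated correlation) and 0.0704, 0.0636 and 0.186 for VPS genes.

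The fall of the plastid genes was weighed against technical causes. Scaling between arrays is argued against, since the median change averaged over genotypes was −0.481 relative to that of all probe sets in the scaling nearest 0, −0.521 with arrays centred on their medians and −0.545 with the values as deposited. A general fall of bright probe sets is argued against too: in 10000 random lists matched on mean value, 95% of medians lay between −0.129 and 0.156. The median of the plastid genes was at percentile 0, which is no test of their fall. They were chosen after that fall was seen, and random lists do not carry the correlation between them. RNA quality stays open: within groups, the mean of the plastid genes had r = −0.00522 with the GAPDH ratio over 18 arrays (permutation p = 0.98, adjusted 0.98 over 2 relations; rho = −0.0918, p = 0.757; r = −0.247 without the 2 farthest), while the ratio itself differed between lights. UV may act on the plastid transcripts, which was not tested apart from RNA quality. How the cRNA labelling captures plastid transcripts was not tested either, so a fall of their signal is not shown to be a fall of their abundance.

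Some named genes differed widely between single plants of 1 group. The SD within groups was 3.45 for AT3G02480, 2.51 for SAG29, 2.3 for AT3G17520 and 2.1 for LEA4-5, a late embryogenesis abundant protein. AT3G02480 had log2 values of 4.91, 4 and 13.51 in the 3 tt4 plants under UV and 5.17, 10.82 and 4.33 in those of sng1. In the fixed list of abscisic acid, cold and drought responses the median SD within groups was 0.74. This lay at percentile 99.99 of random lists matched on mean value (95% between 0.0958 and 0.338), and no gene of that list was dim (mean log2 values of 9.93 to 11.5). The list held only 3 measured genes, and 0.74 was the SD of COR15B. Single arrays weighed on it: COR15B had 7.63 in tt4_CO 3 against 10.21 and 10.67 in the other tt4 plants in CO. The genes did not move as one. In tt4_UV 3 COR15B was lowest of its group (9.075), while COR15A (11.59) and COR47 (13.06) were highest. AT3G02480, SAG29, AT3G17520 and LEA4-5 were at the floor on 7, 2, 11 and 6 of 18 arrays, and in tt4_UV 3 they had 13.51, 12.16, 11.08 and 10.42. Noise of single dim probe sets, which would not be shared, is argued against: over pairs of the 15 genes of widest spread the median correlation of deviations within groups was 0.732 (at least 0.703 without any 1 array), against at most 0.199 in 10000 shuffles of arrays within groups. RNA quality stays open (r = 0.226 within groups over 18 arrays, permutation p = 0.247, adjusted 0.494; rho = 0.17, p = 0.555; r = 0.244 without the 2 farthest), and differences in water status between single plants could give such a pattern but were not tested.

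Of 8 measured ATG genes, which act in autophagy, none was called between tt4 and WT under UV, but their median was 0.23 higher in tt4 (camera adjusted p = 3.49e-05, adjusted p = 0.0167 with an estimated correlation, fry 0.0148). With an estimated correlation the adjusted p was 0.0601 with arrays centred on their medians, where fry gave 0.0678, and 0.0154 with the values as deposited. It was 0.0744 without WT_UV 2, 0.0521 without WT_UV 3, 0.061 without tt4_UV 1 and 0.122 without tt4_UV 3. In CO their median was 0.19 higher in sng1 than in WT, again with none called (camera adjusted p = 0.000212, adjusted p = 0.0322 with an estimated correlation, fry 0.0443). Between tt4 and WT in CO the median was 0.02 (camera adjusted p = 0.8, fry 0.705), and between sng1 and WT under UV it was 0.12 (camera adjusted p = 0.112, fry 0.465). With an estimated correlation the adjusted p of sng1 minus WT in CO was 0.0488 with arrays centred on their medians, where fry gave 0.092, and 0.0177 with the values as deposited. That value was 0.1 without WT_CO 1, 0.209 without WT_CO 2, 0.0668 without WT_CO 3, 0.066 without sng1_CO 1 and 0.129 without sng1_CO 3. The ATG genes were picked from 29 families tested, after the values were seen, so the p-values of camera and fry are no separate test of them.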
